A study of Mus musculus with 8 samples.

How the data were processed

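RNA-seq expression was measured in 8 libraries of sorted mouse lymphocytes, in 4 groups of 2: gut ILC2s of untreated mice, and gut, MLN and lung iILC2s on day 4 after IL-25. Per the labels' protocols, RNA was extracted with a miRNeasy Micro kit and libraries were made with a NEB kit for single cells or low input. The authors deposited FPKM values, fragments scaled to gene length and to the library's number of fragments, to 3 decimals, with 1 column per library and none pooled. The unit is taken from the deposited table's name and from its values, whose sums differ between libraries. The genome build was mm10, per the submitters' processing notes. The aligner, the counting method, the annotation and which fragments entered the library total are not given in the sources used here. Read depth is therefore unknown, and a value of 0 means only that a gene is listed at 0. FPKM are relative values, so a few abundant genes in a library lower all of its others. Reads shared by similar or near-identical genes (the Defa and Reg3 families, Hspa1a and Hspa1b, the globins) may be split between them in an unknown way.

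Values were taken as deposited and analysed as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. Of 18768 genes, 11821 with an FPKM of 1 or more in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3. The model had 4 group means over all 8 libraries, with 4 residual degrees of freedom, 3.32 prior degrees of freedom and a trend of variance with expression. All tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold within each of 4 comparisons: gut iILC2 against gut ILC2, MLN and lung iILC2 each against gut iILC2, and lung against MLN iILC2. The model, the gene lists, the rule for named genes and all alternatives but those called added were chosen before the data were examined. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it. Of 33 lists, those with at least 3 tested members entered, adjusted over the lists of a comparison.

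Named genes were, per comparison, the 8 largest rises and 8 largest falls past the threshold whose libraries did not overlap and whose mean was at least 5 FPKM in the higher group. Predicted models, immunoglobulin and T cell receptor segments, histones, pseudogenes and small RNAs were left out of these. To them were added S1pr1 to S1pr5, Klrg1, Il1rl1 and up to 4 members of each list with the smallest p. The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, a variance prior without the trend or robust, a fit of only the 4 libraries compared, a replicate block and leaving out each library in turn. Where that left a group with 1 library, it was assumed to vary like the other groups. A correction for GC content and transcript length, which 11722 of the 11821 genes had, and a test of genes seen in the MLN and lung libraries were added after the data were seen.

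The steps were tested on simulated data for gut iILC2 against gut ILC2, in 20 runs of 11821 genes with 200 changed. Of genes changed by 1 on the log2 scale 45.5% were recovered, and of those changed by 2, 94.2%. Among calls 5.93% were false. A raised list of 20 genes was found in 100% of runs, and 0.625% of unchanged lists were called. The changed genes all had a mean log2(FPKM + 1) above 2 and were far fewer than those called in the data. Each gene varied independently, so the list rates do not cover lists whose members vary together. For the overlap of the comparisons against gut iILC2s, 100 sets of 8 libraries were simulated without any group difference. The same simulated gut iILC2s served both comparisons.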

Results

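Expression was measured by RNA-seq in sorted group 2 innate lymphoid cells (ILC2s) of wild-type C57BL/6 mice. ILC2s are tissue lymphocytes that lack antigen receptors and secrete type 2 cytokines. Inflammatory ILC2s (iILC2s) are a KLRG1-positive, ST2-negative population that appears after the cytokine IL-25 is given. The 8 libraries fell into 4 groups of 2: gut ILC2s of untreated mice, sorted as KLRG1-positive and ST2-positive, and iILC2s taken on day 4 after IL-25 from the gut, the mesenteric lymph node (MLN) and the lung. Values were deposited as FPKM for 18768 genes, and their sum per library ran from 398570 to 489792. Between 9798 and 11705 genes reached an FPKM of 1 in a library. Read depth is unknown, so no counting interval could be given. Across genes, which are not independent replicates, Spearman's rho was 0.955 to 0.973 between replicates and 0.809 to 0.963 between groups. The first principal component held 71.8% of the variance. It placed the gut ILC2 libraries at -109 and -101, the gut iILC2 libraries at -10.0 and -15.3, the lung libraries at 52.1 and 52.0 and the MLN libraries at 66.5 and 64.6. The labels do not say that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. A permutation test of 2 libraries against 2 has only 3 distinct splits, so all p-values came from limma models over all genes. Over all tested genes, both libraries of 1 group lay above both of the other in 57.6% to 68.7% of genes in the 4 comparisons, a separation that chance gives in 33.3%.

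The series title concerns receptors for sphingosine 1-phosphate (S1P), a lipid gradient that lymphocytes follow out of tissue. S1pr1 was at 5.50 ± 0.203 FPKM in gut ILC2s, 32.3 ± 0.133 in gut iILC2s, 117 ± 2.21 in MLN iILC2s and 184 ± 17.1 in lung iILC2s (SD, n = 2 per group). S1pr4, a receptor largely restricted to leukocytes, was at 5.62 ± 0.18, 36.6 ± 5.07, 177 ± 33.6 and 225 ± 19.3 FPKM in the same order (SD, n = 2 per group). In gut iILC2s against gut ILC2s, S1pr1 rose by 2.36 on the log2 scale (SE 0.13, limma adjusted p = 0.00013) and S1pr4 by 2.50 (SE 0.18, limma adjusted p = 0.00023). From gut to MLN iILC2s, S1pr1 rose by 1.82 (limma adjusted p = 0.0004) and S1pr4 by 2.24 (limma adjusted p = 0.00061). From gut to lung iILC2s, S1pr1 rose by 2.47 (limma adjusted p = 0.00066) and S1pr4 by 2.59 (limma adjusted p = 0.00096). Between lung and MLN the S1pr1 difference was 0.65 (SE 0.13), which missed the threshold over all genes (limma adjusted p = 0.057) and passed adjusted over the list alone (0.0053). It also passed among genes with a mean FPKM of 5 or more (limma adjusted p = 0.041), with adjusted p values of 0.041 to 0.45 over 18 alternatives. The S1pr4 difference between lung and MLN was 0.35 (limma adjusted p = 0.37). S1pr2 lay between 2.63 and 5.48 FPKM in every group. It passed in no comparison except gut iILC2s against gut ILC2s after a correction for GC content and length, where its log2 difference was 0.64 (limma adjusted p = 0.042) against 0.39 without it (0.13, and 0.042 to 0.32 over 17 alternatives). S1pr3 was at 2.01 ± 0.888 FPKM in gut ILC2s and 0.677 ± 0.269 in gut iILC2s (limma adjusted p = 0.055), and it passed adjusted over the list alone (0.032). It also passed with median-of-ratios scaling (limma adjusted p = 0.025), without the variance trend (0.0499), without gut ILC2 replicate 2 (0.028) and after the GC content and length correction (0.043), in a range of 0.025 to 0.21 over 17 alternatives. RNA of other cells in the gut ILC2 libraries may add to the higher S1pr3 value there, which was not tested. S1pr5 was too low to be tested. In the GENCODE M21 annotation of GRCm38 (mm10), S1pr1 is a protein-coding gene on chromosome 3 at 115710433 to 115715072, minus strand, and S1pr4 one on chromosome 10 at 81497747 to 81500132, minus strand.

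**Figure D1:**
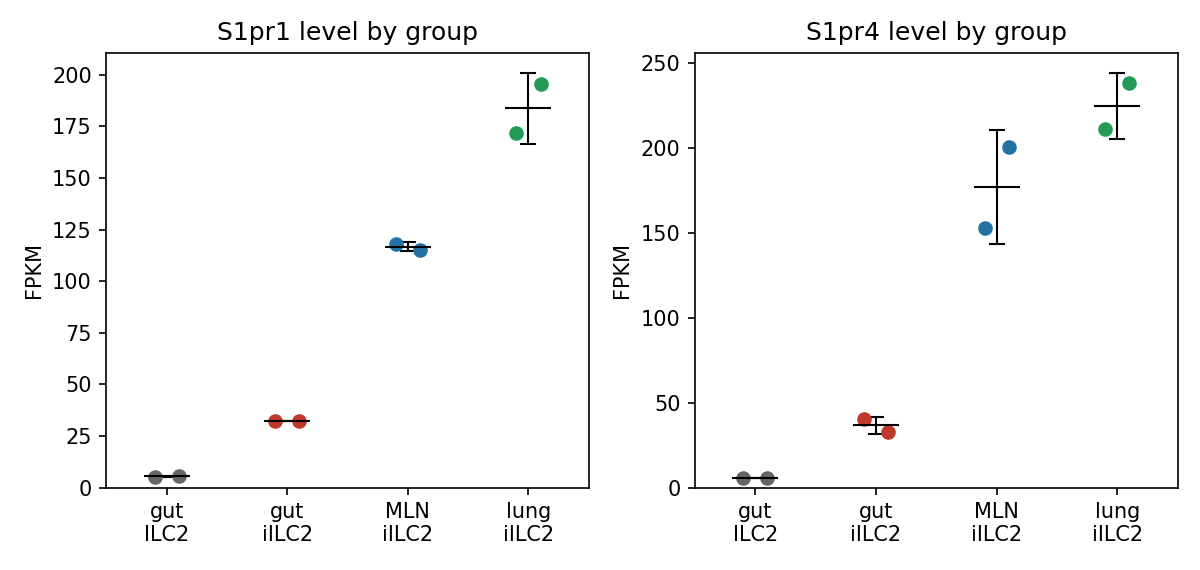
FPKM of S1pr1 and S1pr4 in each library (points) with the group mean and SD (n = 2 per group) for gut ILC2s and for gut, MLN and lung iILC2s. S1pr1 group means were 5.50, 32.3, 117 and 184 FPKM, and S1pr4 means were 5.62, 36.6, 177 and 225 FPKM.

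The list of 5 S1P receptors, with 4 tested, had 2 members that rose and none that fell in each comparison against gut iILC2s. Its camera test passed in MLN against gut (adjusted p = 0.049) and in lung against gut (adjusted p = 0.021). With an estimated correlation the values were adjusted p = 0.31 with an estimated correlation for MLN and adjusted p = 0.37 with an estimated correlation for lung. The counts adjusted over the list alone were also 2 and 0 in both. After a correction for GC content and length neither passed (camera adjusted p = 0.26 and 0.11), and the MLN call was also lost without either gut ILC2 library (0.086), gut iILC2 replicate 1 (0.089) or either lung library (0.055). It was lost too with a pseudocount of 0.1 (0.054), median-of-ratios scaling (0.054), quantile normalization (0.055) and the replicate block. In gut iILC2s against gut ILC2s, 2 of 4 rose and the list did not pass (camera adjusted p = 0.091), with 2 rising and 1 falling adjusted over the list alone, although it passed with fry (adjusted p = 0.00014). Between lung and MLN no member changed over all genes and 1 rose adjusted over the list alone (camera adjusted p = 0.038, and adjusted p = 0.26 with an estimated correlation). That call was lost without MLN replicate 1 (camera adjusted p = 0.072) or lung replicate 2 (0.071), with quantile normalization (0.055) and after the GC content and length correction (0.064).

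Gut iILC2s differed from gut ILC2s in dividing-cell genes, type 2 effector genes and genes of other tissue cells. The groups differed in treatment, in the ST2 gate and in cell state together. Ctla4, an inhibitory co-receptor, was 35.3-fold higher in gut iILC2s, at 737 ± 326 against 20.3 ± 10.9 FPKM (SD, n = 2). Lgals1, which encodes galectin-1, was 34.1-fold higher (2029 ± 503 against 58.6 ± 15.4). Tnfrsf8, the TNF-family receptor CD30, stood at 31.5 ± 0.383 against 0.137 ± 0.0304 FPKM. The chemokine gene Ccl1 was 57.3-fold lower, at 1.99 ± 1.20 against 164 ± 27.5 FPKM, and Tgm2, a transglutaminase, was 33.0-fold lower. In the checkpoint and co-stimulation list 3 of 21 rose and 8 fell (5 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.16) except without gut ILC2 replicate 1 (0.041). Folds throughout are on the log2(FPKM + 1) scale, which understates changes of low genes.

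Of 11821 genes tested, 5014 changed between gut iILC2s and gut ILC2s (limma, Benjamini-Hochberg), 2868 higher and 2146 lower. At least 2-fold changes numbered 1379 higher and 1583 lower. The replication genes Rrm2 (ribonucleotide reductase), Pclaf and Cdc6 were among the largest rises, at 27.3-fold, 18.7-fold and 15.8-fold. Rom1 and the lymphocyte membrane gene Ms4a4b rose 16.5-fold and 14.9-fold. In the mitotic cell cycle list, 37 of 40 tested members rose and none fell (38 and 0 adjusted over the list alone), with a median log2 difference of 2.81 (camera adjusted p = 4.7e-17, but adjusted p = 0.26 with an estimated correlation). Mcm5 and Mcm3, subunits of the replicative helicase, were at 155 ± 8.79 and 204 ± 20.6 FPKM in gut iILC2s against 13.0 ± 0.801 and 20.1 ± 0.689 in gut ILC2s (SD, n = 2).

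The glycolysis, oxidative phosphorylation, actin and ribosome biogenesis lists were also higher in gut iILC2s. In the glycolysis list 14 of 20 members rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.0019, and adjusted p = 0.26 with an estimated correlation). Pkm and Eno1, enzymes of the last steps, rose 3.34-fold and 2.95-fold. In the oxidative phosphorylation list 23 of 29 rose and none fell (25 adjusted over the list alone; camera adjusted p = 2.5e-06, and adjusted p = 0.28 with an estimated correlation), among them Cox5b at 2.17-fold and Sdhb at 2.07-fold. In the actin and motility list 24 of 33 rose and 1 fell (25 and 1 adjusted over the list alone; camera adjusted p = 8.9e-07, and adjusted p = 0.26 with an estimated correlation). Vim, an intermediate filament protein, rose 5.20-fold and the myosin gene Myo1g 3.56-fold. In the ribosome biogenesis list 11 of 25 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.36 with an estimated correlation). This call was lost without gut ILC2 replicate 1 (camera adjusted p = 0.068), without gut iILC2 replicate 2 (0.092) and with quantile normalization (0.18). Nhp2, a small nucleolar ribonucleoprotein, rose 2.60-fold, while Odc1, the first enzyme of polyamine synthesis, was the member that fell, from 39.7 ± 0.861 to 8.74 ± 0.851 FPKM.

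Homing and adhesion genes moved both ways in gut iILC2s. In the chemokine and chemoattractant receptor list 1 of 17 rose and 7 fell (1 and 7 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.052). It passed without gut ILC2 replicate 1 (camera adjusted p = 0.014), without gut iILC2 replicate 1 (0.038), without any 1 of the MLN and lung libraries (0.044 to 0.049) and after the GC content and length correction (0.033). The member that rose was Ccr9, the receptor that brings lymphocytes to the small intestine, by 9.67-fold to 287 ± 58.1 FPKM, while Cxcr3 was at 0.0345 ± 0.0488 against 3.43 ± 0.549 FPKM (SD, n = 2). In the integrin and adhesion list 5 of 22 rose and 8 fell (5 and 10 adjusted over the list alone), with a median log2 difference of -0.72. That list did not pass (camera adjusted p = 0.072), except with quantile normalization (0.040) and with fry (0.047). In the tissue egress list 4 of 12 rose and 2 fell (4 and 3 adjusted over the list alone), and it did not pass (camera adjusted p = 0.55) except with fry (0.014). The integrin gene Itga4 rose 2.26-fold and the junctional adhesion gene Jaml fell 5.45-fold.

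Genes of ILC2 effector function and identity were lower in gut iILC2s. In the type 2 cytokine and effector list 14 of 20 members fell and none rose (15 fell and 1 rose adjusted over the list alone; camera adjusted p = 3.4e-05, and adjusted p = 0.26 with an estimated correlation). Calca, which encodes the peptide CGRP, fell 6.47-fold from 1417 ± 577 FPKM. Dgat2, a triglyceride synthesis enzyme, fell 8.33-fold and Il2 6.63-fold. In the ILC2 identity list 15 of 26 fell and 2 rose (15 and 3 adjusted over the list alone; camera adjusted p = 0.0014, and adjusted p = 0.26 with an estimated correlation). Il17rb, a subunit of the IL-25 receptor, fell 2.99-fold to 117 ± 0.403 FPKM, the nuclear receptor gene Rxrg 6.80-fold and the stem cell factor receptor gene Kit 3.62-fold. In the neuropeptide and alarmin receptor list 10 of 22 fell and none rose (10 and 0 adjusted over the list alone; camera adjusted p = 0.0042, and adjusted p = 0.26 with an estimated correlation). Its members Il4ra and Ramp3, a subunit of peptide hormone receptors, fell 5.02-fold and 4.67-fold. This list did not pass without gut ILC2 replicate 2 (camera adjusted p = 0.09).

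The genes behind the sort markers moved as follows. Il1rl1, which encodes ST2, was at 8.01 ± 4.65 FPKM in gut iILC2s and 39.7 ± 17.8 in gut ILC2s (SD, n = 2), a log2 difference of -2.21 (limma adjusted p = 0.027). That call was lost without gut ILC2 replicate 2 (limma adjusted p = 0.14), without gut iILC2 replicate 2 (0.12) and with no filter on low values (0.061). Klrg1 was at 928 ± 259 against 477 ± 164 FPKM (limma adjusted p = 0.038). Its call was lost without gut ILC2 replicate 1 (limma adjusted p = 0.19), gut iILC2 replicate 1 (0.18) or either lung library (0.065). It was also lost with no filter on low values (0.078), median-of-ratios scaling (0.10) and a fit of only these 4 libraries (0.094). The replicate block (limma adjusted p = 0.051) and the GC content and length correction (0.082) ended it too.

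The ILC3, NK, NF-kB, immediate early and tissue retention lists were lower in gut iILC2s. So were markers of other cells: T cell markers held 0.0842% and 0.0645% of summed FPKM in gut ILC2s and 0.0297% and 0.0232% in gut iILC2s. RNA of other cells in the gut ILC2 libraries may therefore add to these falls, which was not tested. In the ILC3 and type 17 list 10 of 17 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.26 with an estimated correlation). Ltb, a lymphotoxin gene, fell 13.2-fold, Il22 16.7-fold and the IL-23 receptor gene Il23r 5.74-fold. The Il22 fold was 29.7 or 9.44 without gut ILC2 replicate 1 or 2. In the NK and ILC1 list 9 of 14 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.00067, and adjusted p = 0.26 with an estimated correlation). Tbx21, which encodes T-bet, fell 7.13-fold and Ifng 5.67-fold. In the NF-kB and TNF list 16 of 22 fell and none rose (19 and 0 adjusted over the list alone; camera adjusted p = 4e-07, and adjusted p = 0.26 with an estimated correlation), including Nfkbie at 3.72-fold and Relb at 3.36-fold. In the immediate early and dissociation stress list 16 of 26 fell and 2 rose (19 and 2 adjusted over the list alone; camera adjusted p = 2.5e-05, and adjusted p = 0.26 with an estimated correlation). Fos, an AP-1 subunit, was at 200 ± 21.8 against 717 ± 5.16 FPKM and Atf3 at 48.6 ± 0.0594 against 243 ± 49.0 (SD, n = 2). In the tissue retention list 7 of 15 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.26 with an estimated correlation), among them Nr4a3, which fell 4.73-fold.

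Markers of other cell types moved with the same groups. In the intestinal epithelium list 24 of 26 tested members were lower in gut iILC2s and none higher (24 and 0 adjusted over the list alone; camera adjusted p = 2.9e-09, and adjusted p = 0.26 with an estimated correlation). The 28 epithelium markers made up 3.59% and 1.81% of summed FPKM in the gut ILC2 libraries and 0.273% and 0.507% in the gut iILC2 libraries. They held 0.00158% to 0.00205% in the MLN and lung libraries. The 24 defensin genes of the Defa family, products of Paneth cells, held 4.00% and 1.99% in gut ILC2s and 0.0625% and 0.819% in gut iILC2s. Defa29 fell 44.4-fold and Defa22, Defa21, Lyz1 and Reg3g by 39.7-fold, 35.2-fold, 35.1-fold and 29.8-fold. The members of the Defa and Reg3 families resemble each other to differing degrees, so the share of reads given to each is uncertain. Without gut iILC2 replicate 1 or 2 the folds were 24.8 or 79.6 for Defa29, 10.4 or 152 for Defa22, 8.72 or 142 for Defa21, 8.05 or 153 for Lyz1 and 93.4 or 9.47 for Reg3g. The Lyz1 call was lost without gut ILC2 replicate 1 (limma adjusted p = 0.054). In the fibroblast, endothelial and smooth muscle list 20 of 25 fell and 1 rose (22 and 1 adjusted over the list alone; camera adjusted p = 3.1e-07, and adjusted p = 0.26 with an estimated correlation). Dcn and Lum, proteoglycans of connective tissue, fell 32.5-fold and 18.0-fold. In the macrophage, monocyte and dendritic cell list 12 of 17 fell and none rose (12 and 0 adjusted over the list alone; camera adjusted p = 9.2e-05, and adjusted p = 0.26 with an estimated correlation), among them the complement gene C1qc at 12.4-fold.

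**Figure D2:**
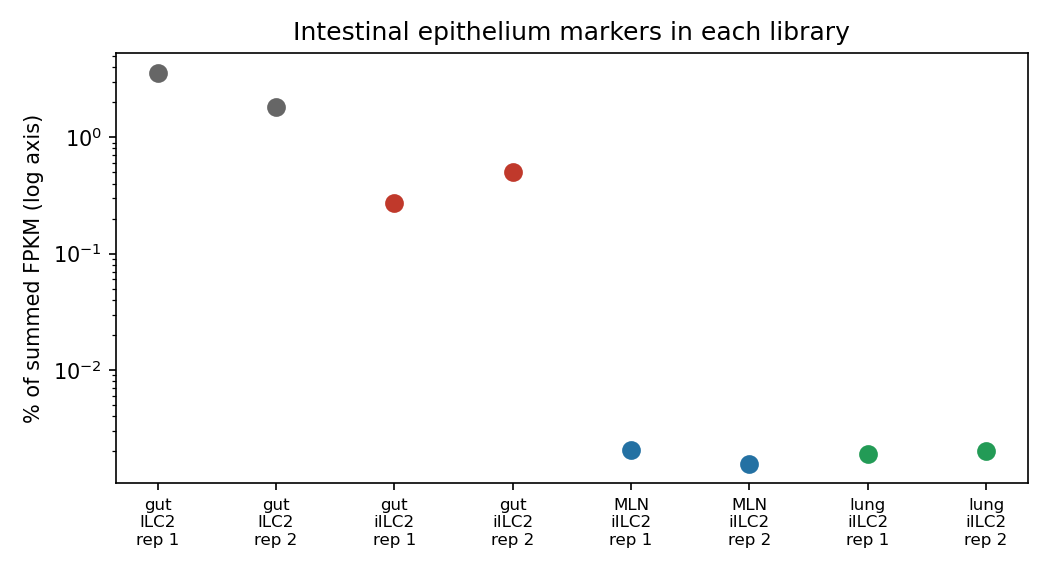
Percent of summed FPKM held by the 28 intestinal epithelium markers in each of the 8 libraries, on a log axis. The gut ILC2 libraries lie at 3.59% and 1.81%, the gut iILC2 libraries at 0.273% and 0.507%, and the MLN and lung libraries between 0.00158% and 0.00205%.

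Median-of-ratios scaling shifted the median of all genes by -0.133 and gave 2278 higher and 2634 lower, and testing all genes with no filter on low values shifted it by -0.105 and gave 2689 higher and 2806 lower. Among the 9965 genes with a mean FPKM of 1 or more over the MLN and lung libraries, a choice made after the data were seen, 3892 changed, 2840 higher and 1052 lower. That filter leaves out genes seen mainly in gut ILC2s, so a larger share of higher genes was built into it.

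MLN iILC2s differed from gut iILC2s in early response genes, effector genes and epithelial transcripts. This comparison asked how iILC2s in a draining lymph node differed from those in the gut at the same day. Fos was at 0.620 ± 0.494 FPKM in MLN iILC2s and 200 ± 21.8 in gut iILC2s (SD, n = 2), a 126-fold difference. Rgs2, a regulator that shortens G protein signals, was 116-fold lower and Calca 138-fold lower in MLN iILC2s. Osbpl5, a lipid transfer protein, was 11.2-fold higher at 28.6 ± 1.72 against 1.66 ± 0.389 FPKM, and Ccnf, which encodes cyclin F, was 10.5-fold higher.

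Between these groups 2725 of 11821 genes changed (limma, Benjamini-Hochberg), 1654 higher and 1071 lower in the MLN. Of these, 817 higher and 757 lower genes differed at least 2-fold. Nod1, a sensor of bacterial peptidoglycan, rose 7.80-fold and the adaptor gene Sh2d3c 6.57-fold. Fam78a and the transcription factor gene Msc rose 6.66-fold and 7.89-fold. Lfng, which modifies Notch receptors, rose 8.59-fold, and its call was lost without MLN replicate 1 (limma adjusted p = 0.062). Gpr15, a homing receptor for the large intestine, rose 8.32-fold to 23.7 ± 19.8 FPKM (15.8-fold or 4.38-fold without MLN replicate 1 or 2). Its call was lost without MLN replicate 2 (limma adjusted p = 0.12), without gut iILC2 replicate 2 (0.088) and with no filter on low values (0.069). Gpr15 was the 1 member that rose in the chemokine and chemoattractant receptor list, where 8 of 17 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.029, and adjusted p = 0.44 with an estimated correlation). The list call was lost without gut iILC2 replicate 1 (camera adjusted p = 0.089) or MLN replicate 1 (0.084), and with median-of-ratios scaling (0.075) or quantile normalization (0.055).

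The tissue egress list had 6 of 12 members higher in MLN iILC2s and none lower (7 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.31 with an estimated correlation). Besides the S1P receptors, Arhgap45 rose 2.97-fold to 260 ± 47.6 FPKM. In the tissue retention list 9 of 15 fell and none rose (9 and 0 adjusted over the list alone; camera adjusted p = 3.5e-08, and adjusted p = 0.11 with an estimated correlation). The orphan nuclear receptor gene Nr4a1 fell 91.2-fold, Nr4a2 30.3-fold and the cAMP-responsive repressor gene Crem 98.6-fold. Cxcr6, a chemokine receptor of tissue lymphocytes, fell 2.83-fold. In the immediate early list 19 of 26 fell and none rose (19 and 0 adjusted over the list alone; camera adjusted p = 4.7e-14, and adjusted p = 0.11 with an estimated correlation). Atf3 was at 48.6 ± 0.0594 FPKM in gut iILC2s and listed at 0 in both MLN libraries. In the actin and motility list 9 of 33 rose and none fell (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0056, and adjusted p = 0.43 with an estimated correlation), including Myo1g at 3.48-fold and Wipf1 at 2.70-fold. The actin list did not pass without MLN replicate 2 (camera adjusted p = 0.06). In the integrin and adhesion list 6 of 22 rose and 1 fell (6 and 1 adjusted over the list alone), and it did not pass (camera adjusted p = 0.17) except with fry (0.048). Its members Itga4 and Itgb2 rose 3.02-fold and 2.84-fold.

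The type 2 cytokine, ILC2 identity, NF-kB, checkpoint and unfolded protein response lists were lower in the MLN. Handling is not given in the sources used here, so it cannot be told apart from tissue for these lists. In the type 2 cytokine list 10 of 20 fell and none rose (12 and 0 adjusted over the list alone; camera adjusted p = 1e-06, and adjusted p = 0.14 with an estimated correlation). Il5 was at 4.42 ± 0.619 against 245 ± 70.8 FPKM and Areg, an epidermal growth factor family ligand, at 0.194 ± 0.120 against 55.4 ± 32.9 (SD, n = 2). In the ILC2 identity list 7 of 26 fell and 2 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.0038, and adjusted p = 0.40 with an estimated correlation), and Rora fell 5.71-fold. In the NF-kB and TNF list 16 of 22 fell and 1 rose (17 and 1 adjusted over the list alone; camera adjusted p = 3.5e-08, and adjusted p = 0.31 with an estimated correlation). Tnfrsf9, the co-stimulatory receptor 4-1BB, fell 82.9-fold and Rel 22.6-fold. In the checkpoint and co-stimulation list 12 of 21 fell and 1 rose (13 and 2 adjusted over the list alone; camera adjusted p = 1.3e-05, and adjusted p = 0.31 with an estimated correlation), with Pdcd1, which encodes PD-1, 11.5-fold lower (7.31-fold or 18.0-fold without MLN replicate 1 or 2). In the unfolded protein response list 10 of 22 fell and none rose (10 and 0 adjusted over the list alone; camera adjusted p = 7e-07, and adjusted p = 0.29 with an estimated correlation), with Atf4 4.16-fold lower. Il17a was at 75.1 ± 42.8 FPKM in gut iILC2s and listed at 0 in both MLN libraries. In the neuropeptide and alarmin receptor list 4 of 22 rose and 5 fell (4 and 5 adjusted over the list alone), and Ramp3 fell 69.1-fold. That list did not pass (camera adjusted p = 0.075), except without MLN replicate 2 (0.029), after the GC content and length correction (0.034) and with fry (0.040).

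Cell cycle genes were higher in MLN iILC2s. In that list 18 of 40 rose and none fell (23 and 0 adjusted over the list alone; camera adjusted p = 7.2e-07, and adjusted p = 0.48 with an estimated correlation), among them the spindle protein gene Prc1 at 2.21-fold. In the intestinal epithelium list 24 of 26 fell and none rose (24 and 0 adjusted over the list alone; camera adjusted p = 5e-16, and adjusted p = 0.31 with an estimated correlation). Defa6 averaged 1091 ± 1308 FPKM in gut iILC2s and Defa24 885 ± 1062, and both were listed at 0 in both MLN libraries. So were Spink4 (199 ± 179 in gut iILC2s), the disulfide isomerase gene Agr2 (172 ± 131) and the keratin gene Krt8 (102 ± 35.7). In the macrophage, monocyte and dendritic cell list 1 of 17 fell and none rose (0 and 0 adjusted over the list alone; camera adjusted p = 0.035, and adjusted p = 0.48 with an estimated correlation). This call was lost without gut iILC2 replicate 1 (camera adjusted p = 0.39) or MLN replicate 1 (0.060), and with a pseudocount of 0.1 (0.052), median-of-ratios scaling (0.075), quantile normalization (0.13), the GC content and length correction (0.084) and fry (0.23). In the fibroblast, endothelial and smooth muscle list 2 of 25 fell and none rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.0078, and adjusted p = 0.48 with an estimated correlation), a call lost without gut iILC2 replicate 1 (camera adjusted p = 0.089), with quantile normalization (0.13) and with fry (0.17).

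Median-of-ratios scaling shifted the median of all genes by -0.105 and gave 1225 higher and 1259 lower. Leaving out MLN replicate 1 or 2 lowered the count to 724 or 1183 genes, and leaving out lung replicate 1 or 2 to 1778 or 1779.

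Lung iILC2s differed from gut iILC2s in egress and integrin genes and in intestinal epithelial transcripts. The question was how iILC2s in a tissue distant from the gut differed from those in it. Osbpl5 was at 39.3 ± 0.876 FPKM in lung and 1.66 ± 0.389 in gut iILC2s (SD, n = 2), 15.2-fold higher. Nod1 was 14.3-fold higher and Tagap, a GTPase-activating protein of activated T cells, 11.9-fold higher at 128 ± 27.8 FPKM. Ripor2, a RhoA inhibitor in lymphocytes, was 7.75-fold higher at 160 ± 3.22 FPKM. Fos was 3.44-fold higher in the lung at 688 ± 15.8 FPKM, while Calca was 9.74-fold lower and Il5 9.04-fold lower. The Il5 fold was 15.2 or 5.36 without lung replicate 1 or 2.

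Of 11821 genes, 2943 changed (limma, Benjamini-Hochberg), 1855 higher and 1088 lower in the lung, and 967 and 584 of them at least 2-fold. Rap1gap2, Crip2 and the ciliary transcription factor gene Rfx2 rose 9.10-fold, 8.86-fold and 8.29-fold. Tppp3 rose 9.32-fold (18.9-fold or 4.60-fold without gut iILC2 replicate 1 or 2), and its call was lost without lung replicate 1 (limma adjusted p = 0.083) or 2 (0.059). In the egress list 7 of 12 rose and none fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.37 with an estimated correlation), with Arhgap45 3.94-fold higher. In the integrin and adhesion list 8 of 22 rose and none fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.021, and adjusted p = 0.48 with an estimated correlation). Itgb2 rose 4.13-fold, Itga5 5.05-fold and Itga4 2.82-fold. The integrin list did not pass after a correction for GC content and length (camera adjusted p = 0.062). In the actin and motility list 14 of 33 rose and none fell (17 and 0 adjusted over the list alone; camera adjusted p = 1.5e-05, and adjusted p = 0.37 with an estimated correlation), including Myo1f at 4.31-fold and Lsp1 at 3.40-fold. Thy1, a surface glycoprotein of T cells and ILC2s, rose 6.45-fold, in an ILC2 identity list where 3 of 26 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.85).

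The unfolded protein response, ribosome biogenesis and oxidative phosphorylation lists were lower in the lung. In the unfolded protein response list 15 of 22 fell and none rose (15 and 0 adjusted over the list alone; camera adjusted p = 1.7e-09, and adjusted p = 0.37 with an estimated correlation). Herpud1, which acts in protein degradation at the endoplasmic reticulum, fell 3.95-fold and the asparagine synthetase gene Asns 5.61-fold. Chac1 was at 10.6 ± 0.643 FPKM in gut iILC2s and listed at 0 in both lung libraries. In the ribosome biogenesis list 11 of 25 fell and none rose (12 and 0 adjusted over the list alone; camera adjusted p = 1.4e-06, and adjusted p = 0.37 with an estimated correlation), with Mrto4 2.40-fold and Wdr43 2.17-fold lower. In the oxidative phosphorylation list 13 of 29 fell and none rose (17 and 0 adjusted over the list alone; camera adjusted p = 7e-07, and adjusted p = 0.57 with an estimated correlation), with cytochrome c (Cycs) 3.53-fold lower. Dgat1 and Plin2, genes of lipid droplet formation, fell 10.1-fold and 3.45-fold, while the fatty acid transport enzyme gene Cpt1a rose 2.51-fold. They stand in the fatty acid list, where 1 of 22 rose and 5 fell (1 and 6 adjusted over the list alone). That list did not pass (camera adjusted p = 0.10), except without gut iILC2 replicate 2 (0.041) and with fry (0.044).

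In the immediate early list 7 of 26 members rose and 1 fell in the lung (10 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.40), except with fry (0.046). Zfp36 and Egr2 rose 3.49-fold and 3.48-fold. Nor did the tissue retention list pass, with 1 of 15 rising and 2 falling (1 and 2 adjusted over the list alone; camera adjusted p = 0.54), the type 2 cytokine list, with 4 of 20 falling and none rising (2 and 0 adjusted over the list alone; 0.48), or the NF-kB list, with 3 of 22 rising and 9 falling (4 and 9 adjusted over the list alone; 0.44). In the cell cycle list 7 of 40 rose and none fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.0027, and adjusted p = 0.87 with an estimated correlation), a call not seen with fry (adjusted p = 0.25). In the intestinal epithelium list 24 of 26 fell and none rose (24 and 0 adjusted over the list alone; camera adjusted p = 4.2e-16, and adjusted p = 0.37 with an estimated correlation). Defa6 was at 0.146 ± 0.207 FPKM in the lung and Defa24 at 0.117 ± 0.165 (SD, n = 2). Spink4, Agr2, Krt8 and the Paneth cell gene Ang4 fell 145-fold, 119-fold, 86.4-fold and 89.6-fold. Without gut iILC2 replicate 1 or 2 these folds were 305 or 68.5 for Spink4, 65.5 or 215 for Agr2 and 155 or 51.7 for Ang4. Fabp6, an ileal bile acid carrier, and Clca1, a goblet cell product, were at 132 ± 128 and 77.7 ± 8.16 FPKM in gut iILC2s and listed at 0 in both lung libraries.

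Median-of-ratios scaling gave 1522 higher and 1361 lower. Leaving out lung replicate 1 or 2 lowered the count of changed genes to 611 or 652.

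The comparisons of MLN and lung with gut iILC2s shared calls. Genes higher in both numbered 1213, genes lower in both 630, and 16 were called in opposite directions. Osbpl5, Nod1, Arhgap45, Itga4, S1pr1 and S1pr4 were among the genes higher in both, and Calca, Il5, Ramp3, Dgat1 and Krt8 among those lower in both. Independent lists of these sizes would share 259.6 higher and 98.6 lower genes. In 100 simulations with no changed gene, where both comparisons used the same simulated gut iILC2s, 0.01 genes were shared on average. Almost no gene is called without a change, so that count was near 0 in advance and does not gauge the shared controls. The log2 differences correlated across genes at 0.81, against 0.50 in the simulations, with a covariance of 0.626 against 0.0455, a difference of 0.581. The gut iILC2 libraries could not be split with 2 left in each part, so part of the excess may come from the shared controls. Over 11722 genes, the differences of both comparisons also rose with GC content (Spearman 0.243 for MLN and 0.224 for lung). They rose with transcript length too (0.184 and 0.227). In lung against MLN these correlations were -0.00792 and 0.0886. The simulations held no such trend, which may also add to the excess. After the correction for GC content and length 1525 genes were shared. The shared count of 1843 fell to 582 or 847 without MLN replicate 1 or 2 and to 493 or 526 without lung replicate 1 or 2.

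Lung iILC2s differed from MLN iILC2s in early response genes, which were high in the lung and low in the MLN. Here the question was how iILC2s differed between these sites outside the gut. Fos was at 688 ± 15.8 against 0.620 ± 0.494 FPKM (SD, n = 2), 435-fold higher in the lung. Nr4a1 was 186-fold higher at 1181 ± 213 against 5.33 ± 0.937 FPKM, and Rgs2 78.6-fold higher. Cd69, a membrane protein that lowers surface S1PR1 and holds lymphocytes in tissue, was at 772 ± 207 against 17.8 ± 11.5 FPKM, 44.9-fold higher. The heat-shock gene Hspa1a, which has a near-identical copy and is therefore uncertain, was 82.8-fold higher. Without lung replicate 1 or 2 the Hspa1a fold was 131 or 52.2, and without MLN replicate 1 or 2 the Cd69 fold was 28.2 or 71.5.

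Of 11821 genes, 253 changed (limma, Benjamini-Hochberg), 197 higher and 56 lower in the lung, and 180 and 29 of them at least 2-fold. Ppp1r15a, a stress-induced phosphatase subunit, rose 62.2-fold and Rgcc 30.9-fold. In the immediate early list 13 of 26 rose and none fell (22 rose and 1 fell adjusted over the list alone), with a median of 2.76 (camera adjusted p = 9.1e-26, and adjusted p = 0.036 with an estimated correlation). Fosb was at 19.3 ± 2.46 against 0.0130 ± 0.0184 FPKM and Egr2 at 17.2 ± 2.15 against 0.0295 ± 0.0417 (SD, n = 2). In the tissue egress list none of 12 rose or fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.026, and adjusted p = 0.32 with an estimated correlation), a call lost with fry (0.097). In the tissue retention list 8 of 15 rose and none fell (9 and 0 adjusted over the list alone), with a median of 1.83 (camera adjusted p = 1.8e-14, and adjusted p = 0.036 with an estimated correlation). Nr4a2 rose 28.4-fold and Crem 15.1-fold. Cd69, Nr4a1, Nr4a2, Rgs2 and Crem are induced early after activation, and Nr4a1 stands in both lists.

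**Figure D3:**
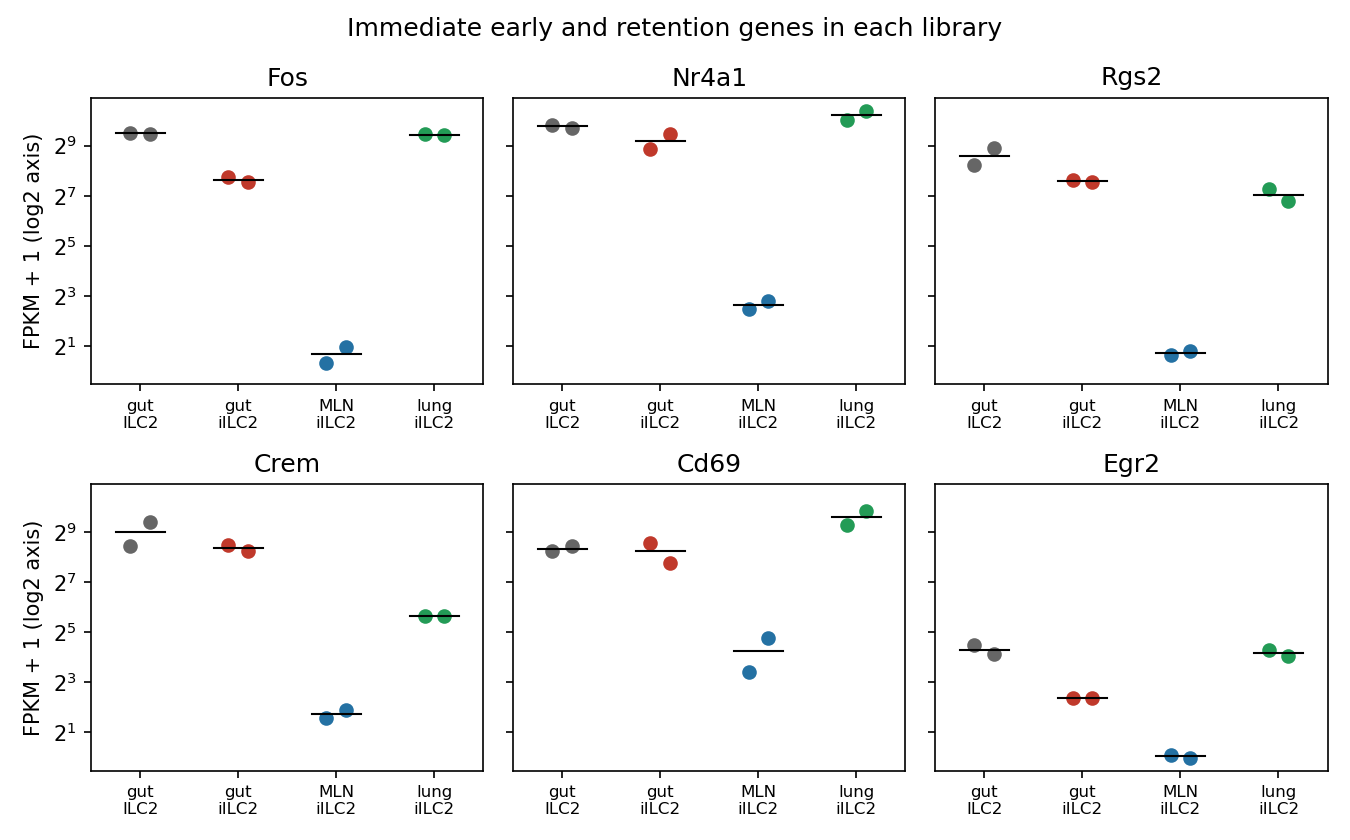
FPKM + 1 on a log2 axis for Fos, Nr4a1, Rgs2, Crem, Cd69 and Egr2 in gut ILC2s and in gut, MLN and lung iILC2s. Points are libraries and lines are group means, and Fos averaged 717, 200, 0.620 and 688 FPKM in the 4 groups.

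In the type 2 cytokine list 5 of 20 rose and none fell in the lung (10 and 0 adjusted over the list alone; camera adjusted p = 2.6e-09, and adjusted p = 0.07 with an estimated correlation). Areg rose 17.3-fold, Il6 10.3-fold and Calca 14.2-fold. Il13 was at 473 ± 88.7 against 38.5 ± 26.7 FPKM (SD, n = 2), a call lost without lung replicate 1 (limma adjusted p = 0.057) or 2 (0.086). Il17a was at 34.8 ± 17.9 FPKM in the lung and listed at 0 in both MLN libraries, and its call was lost without any 1 of the MLN and lung libraries (limma adjusted p = 0.054 to 0.14) and with no filter on low values (0.062). In the NF-kB and TNF list 8 of 22 rose and none fell (16 and 0 adjusted over the list alone; camera adjusted p = 2.4e-14, and adjusted p = 0.17 with an estimated correlation). Nfkbid, an atypical IkB protein gene, rose 13.3-fold and Tnfaip3, which encodes A20, 25.8-fold, and the Tnfaip3 call was lost without MLN replicate 1 (limma adjusted p = 0.055). In the checkpoint and co-stimulation list 2 of 21 rose and none fell (10 and 0 adjusted over the list alone; camera adjusted p = 1.5e-06, and adjusted p = 0.24 with an estimated correlation). In the neuropeptide and alarmin receptor list 3 of 22 rose and none fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.00077, and adjusted p = 0.26 with an estimated correlation). In the ILC2 identity list 2 of 26 rose and none fell (4 and 0 adjusted over the list alone; camera adjusted p = 1.5e-06, and adjusted p = 0.24 with an estimated correlation).

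Among genes lower in the lung, Rsrp1 was at 29.3 ± 7.53 against 183 ± 86.2 FPKM (SD, n = 2), Gcsh of the glycine cleavage system at 5.15 ± 0.257 against 18.4 ± 4.28, and Asns at 4.12 ± 0.865 against 14.3 ± 1.68. The galactokinase gene Galk1 fell 2.80-fold, Etv5 2.74-fold, the tRNA methyltransferase gene Mettl1 2.58-fold, the folate carrier gene Slc19a1 2.57-fold and Pgls of the pentose phosphate pathway 2.57-fold. In the ribosome biogenesis list 1 of 25 fell and none rose (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 3.2e-07, and adjusted p = 0.24 with an estimated correlation).

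Lists of markers of other cell types also moved between these libraries. In the lung epithelium list 1 of 6 members rose and none fell (2 and 0 adjusted over the list alone), with a median log2 difference of 0.74 (camera adjusted p = 0.041, and adjusted p = 0.32 with an estimated correlation). The member that rose was Sftpc, a surfactant gene, at 4.97 ± 1.47 against 0.818 ± 0.0735 FPKM (SD, n = 2), and Napsa was at 9.71 ± 0.921 against 6.46 ± 0.989. The Sftpc call was lost without any 1 of the MLN and lung libraries (limma adjusted p = 0.11 to 0.25), with no filter (0.10), median-of-ratios scaling (0.055) or quantile normalization (0.15), and in a fit of only these 4 libraries (0.085). The list call was lost without either gut ILC2 library (camera adjusted p = 0.054 to 0.055), either MLN library (0.086 and 0.051) or lung replicate 2 (0.14), with quantile normalization (0.081) and with fry (0.097). In the T cell list none of 10 rose or fell (1 and 0 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.041, and adjusted p = 0.32 with an estimated correlation), and Lat was at 75.7 ± 9.43 against 40.7 ± 3.61 FPKM. The T cell call was lost without either MLN library (camera adjusted p = 0.072 and 0.058), without lung replicate 1 (0.071) and with fry (0.12). In the fibroblast, endothelial and smooth muscle list none of 25 rose or fell, nor did any adjusted over the list alone, with a median of 0.43 (camera adjusted p = 0.017, and adjusted p = 0.45 with an estimated correlation). Pecam1, an adhesion gene, was at 58.9 ± 2.53 against 45.7 ± 4.82 FPKM. No other tested member of this list or the lung epithelium list was above 9.71 FPKM in lung. This call was lost without MLN replicate 2 (camera adjusted p = 0.051) or lung replicate 2 (0.47) and with fry (0.26). The other marker lists did not pass: macrophage (camera adjusted p = 0.22), B and plasma cell (0.77), granulocyte (0.19), erythrocyte (0.18) and intestinal epithelium (0.95). Without lung replicate 1 the macrophage (camera adjusted p = 0.018) and erythrocyte (7.8e-05) lists passed.

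The count of 253 was 53 or 103 without MLN replicate 1 or 2, 71 or 61 without lung replicate 1 or 2, and 390 or 393 without gut iILC2 replicate 1 or 2. It was 129 with no filter on low values and 74 in a fit of only these 4 libraries. That last fit ended the calls of Hspa1a, Cd69, Calca, Il6, Il13, Il17a, Nfkbid and Tnfaip3 (limma adjusted p = 0.061 to 0.091). The calls of Rsrp1, Gcsh, Asns, Galk1, Etv5, Mettl1, Slc19a1 and Pgls were lost in it, with no filter and without any 1 of the MLN and lung libraries (0.053 to 0.29), apart from Rsrp1 without MLN replicate 1. Calls of Etv5, Pgls, Rsrp1 and Slc19a1 were also lost without either gut ILC2 library (0.053 to 0.072), and that of Etv5 without either gut iILC2 library (0.053). Without the variance trend the calls of Etv5 (0.0501) and Pgls (0.058) were lost, and after the GC content and length correction that of Pgls (0.064). The replicate block ended those of Etv5 (limma adjusted p = 0.087), Pgls (0.071) and Asns (0.051).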

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

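The GC content and length correction and the test of genes seen in the MLN and lung libraries were chosen only after the results were seen. No named gene difference or list that was called changed direction in any setting run, but the balance of higher and lower genes did. It went from 2868 and 2146 to 2278 and 2634 with median-of-ratios scaling and to 2689 and 2806 with no filter, where more genes were tested, in gut iILC2 against gut ILC2, and from 1654 and 1071 to 1225 and 1259 with median-of-ratios scaling in MLN against gut. The S1pr1 and S1pr4 rises in gut iILC2s against gut ILC2s and in MLN and lung against gut iILC2s passed in all of them. The S1pr1 difference between lung and MLN, 0.65, passed with a mean of at least 5 FPKM (limma adjusted p = 0.041), where fewer genes were tested. A fit of only the 4 libraries compared, with fewer samples, called 2885 genes in gut iILC2 against gut ILC2 and 74 in lung against MLN, and no filter called 129 in lung against MLN, where more genes were tested. Camera with an estimated correlation called 0, 0, 0 and 2 lists in the 4 comparisons, against 24, 17, 9 and 24 at the preset correlation, and fry called 10 in lung against MLN; the cause was not tested. Leaving out 1 library gave 4119 to 4477 genes in gut iILC2 against gut ILC2. It gave 724 (without MLN replicate 1) to 3252 in MLN against gut, 611 (without lung replicate 1) to 3472 in lung against gut and 53 (without MLN replicate 1) to 393 (without gut iILC2 replicate 2) in lung against MLN. Genes shared by the comparisons against gut iILC2s numbered 493 (without lung replicate 1) to 2290. Of 534 named gene values, 367 were called and 243 stayed called without any 1 library, as did 47 of 74 list calls. A mean of at least 5 FPKM gave 2723 higher and 826 lower genes in gut iILC2 against gut ILC2. Replicate deviations correlated at -0.17 to 0.20 over 6 pairs of groups, which cannot show whether the replicate numbers pair the libraries. With the replicate block 4906, 2518, 2757 and 176 genes were called and 1727 shared. With the block, 4 calls were lost and 2 gained over 128 list tests, and 21 were lost and 10 gained over the 534 named gene values. Unknown depth leaves the precision of low values unknown.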

Other observations

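All tests of explanations below were chosen only after the results were seen. In the list of genes for S1P metabolism and transport, 5 of 13 tested members fell in gut iILC2s against gut ILC2s and none rose (6 and 0 adjusted over the list alone; limma camera adjusted p = 0.012, and adjusted p = 0.35 with an estimated correlation), a call lost without gut iILC2 replicate 2 (0.092). Plpp3, a lipid phosphatase, was at 0.682 ± 0.395 against 4.19 ± 0.426 FPKM and the S1P phosphatase gene Sgpp2 at 1.48 ± 0.562 against 7.64 ± 4.37 (SD, n = 2). RNA of other cells in the gut ILC2 libraries may add to the falls in this list, which was not tested. Of 21 interferon-stimulated genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; limma camera adjusted p = 0.013, and adjusted p = 0.32 with an estimated correlation), a call lost without gut ILC2 replicate 2 (0.10) or gut iILC2 replicate 2 (0.11). Irf7, an interferon regulatory factor, fell 2.72-fold while Ifi27l2a rose 3.87-fold. Of 22 fatty acid genes 4 rose and 7 fell (4 and 7 adjusted over the list alone; limma camera adjusted p = 0.24, and 0.028 with quantile normalization), and of 20 cholesterol genes 4 rose and 2 fell (3 and 1 adjusted over the list alone; limma camera adjusted p = 0.91). Of 22 unfolded protein response genes 11 rose and 1 fell (11 and 2 adjusted over the list alone; limma camera adjusted p = 0.042, and adjusted p = 0.35 with an estimated correlation). That call was lost without gut ILC2 replicate 1 or gut iILC2 replicate 2, with a pseudocount of 0.1 (limma camera adjusted p = 0.059) and with median-of-ratios scaling (0.077). Quantile normalization (0.63), the GC content and length correction (0.11) and the replicate block also ended it.

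Markers of further cell types in the same comparison were as follows. Of 10 T cell markers 6 fell and none rose (6 and 0 adjusted over the list alone; limma camera adjusted p = 0.0013, and adjusted p = 0.26 with an estimated correlation). Of 9 B and plasma cell markers 8 fell and 1 rose (8 and 1 adjusted over the list alone; limma camera adjusted p = 0.019, and adjusted p = 0.35 with an estimated correlation), a call lost without gut iILC2 replicate 2 (0.092) and with fry (0.16). The riser, Cd79b of the B cell receptor, stood at 111 ± 7.59 against 24.1 ± 2.66 FPKM (SD, n = 2). Of 5 granulocyte markers 3 fell and none rose (4 and 0 adjusted over the list alone; limma camera adjusted p = 0.030, and adjusted p = 0.26 with an estimated correlation), a call lost without gut ILC2 replicate 2 (0.051) or gut iILC2 replicate 2 (0.11), with median-of-ratios scaling (0.060) and with quantile normalization (0.099). Of 6 lung epithelium markers 4 fell and none rose (4 and 0 adjusted over the list alone; limma camera adjusted p = 0.018, and adjusted p = 0.26 with an estimated correlation), a call lost without gut iILC2 replicate 2 (0.068). Of 6 erythrocyte markers 2 fell and none rose (2 and 0 adjusted over the list alone; limma camera adjusted p = 0.023, and adjusted p = 0.42 with an estimated correlation), a call lost without gut ILC2 replicate 2 (0.19) or gut iILC2 replicate 1 (0.058) and with fry (0.11). Of the 3 sort gate genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; limma camera adjusted p = 0.72), and Ptprc, which encodes CD45, was at 167 ± 32.7 against 184 ± 36.7 FPKM (SD, n = 2). Of 13 mitochondrially encoded genes 0 were in the table used here. Median, mean and test differed in sign only in lists that did not pass, such as cholesterol biosynthesis and the B cell markers in lung against gut.

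Epithelial and Paneth cell transcripts stood in the gut libraries although the gate took CD45-positive cells negative for lineage markers, which would remove epithelial cells. Reads shared within the Defa and Reg3 families are argued against as the whole source, since 23 markers outside them had a median log2 difference between MLN and gut iILC2s of -3.62 (median absolute deviation 1.78). All 26 tested markers were higher in every gut library than in every MLN and lung library, against 13.6% of all tested genes. RNA of epithelial cells carried into the gut sorts cannot be told apart from expression by the sorted cells, which would give the same count. The ratio between replicates varied over the markers with a median absolute deviation (log2) of 0.40 in gut ILC2s and 0.79 in gut iILC2s. This does not settle it, because carried-over epithelial cells could differ in mix between replicates.

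Immediate early genes were low in MLN iILC2s and higher in the lung, with a median log2 difference of 2.76. GC content and length are argued against, since the median was 2.69 after correction. RNA of other cells carried into the lung sorts, although the gate would remove them, cannot be told apart from expression by the sorted cells, because 3 of 8 marker lists passed camera upward but weakly: lung epithelium (median 0.74, 1 of 6 rose, adjusted p = 0.32 with an estimated correlation), T cell (0.45, 0 of 10, adjusted p = 0.32 with an estimated correlation) and fibroblast, endothelial and smooth muscle (0.43, 0 of 25, adjusted p = 0.45 with an estimated correlation), none of which passed with fry (0.097, 0.12 and 0.26). Dissociation or handling of gut and lung tissue cannot be told apart from tissue, because handling is not given in the sources used here and would go with the tissue, and 7 heat-shock members had a median of 0.760 (median absolute deviation 0.830), with 1 that rose. A difference between tissues stays open and untested. Handling would go with the tissue in every list compared between tissues.

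S1pr1 and S1pr4 were higher in MLN and lung than in gut iILC2s. A fall of all genes alike in the gut libraries is argued against by 6985 genes with a mean FPKM of 5 or more in MLN and lung. Their median log2 difference between MLN and gut was 0.163 (median absolute deviation 0.623), against 1.82 for S1pr1. Dilution of the gut libraries by RNA of other cells is argued against as the whole source. Most gut iILC2 RNA would then have to come from other cells. Epithelium markers held 0.273% and 0.507% of summed FPKM there, against 3.59% and 1.81% in gut ILC2s. Macrophage, monocyte and dendritic cell markers held 0.0576% and 0.0639%, against 0.0452% to 0.0533% in MLN and lung. Shares of the other marker lists did not exceed the highest in MLN and lung. A part from dilution stays open, because genes that such cells also express need not fall with it. GC content and length are argued against, since the smallest difference was 1.88 after correction. Loss of S1pr1 in the handling that raises early genes cannot be told apart from tissue, because handling would go with the tissue. S1pr1 was higher in lung, where early genes were high, than in MLN by 0.65 (SE 0.13), which missed the threshold (limma adjusted p = 0.057). A loss in gut tissue alone also stays open. A difference of tissue or cell state may be a further explanation and was not tested.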
